A study of Homo sapiens with 4 samples.

How the data were processed

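Per the labels, cells of MDA-MB-231 and MDA-MB-453 were kept in medium with 10% serum and then spent 24 h on growth factor reduced matrigel with 0% or 10% serum. Total RNA was extracted with Trizol, poly(A) RNA was selected with oligo-dT beads, and libraries were made with a TruSeq RNA kit and read as single reads. Whether the kit kept strand is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. Each of the 4 libraries is the 1 sample of its group, with no replicate.

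Per the submitters' processing notes, the tools named were CASAVA 1.8.2, Bowtie 1.0.0 and DESeq2, with build hg19, and the role and version of DESeq2 are not given. The read counter, its strand and multiple-mapping settings and the annotation release are not given in the sources used here. The deposited tables hold raw read counts for 31402 RefSeq transcripts per library, a further read count that is never above the first, and an RPKM value. The tables have no header, so these units were read from the values. The authors' RPKM was found to be the first deposited count divided by 1 library factor and 1 transcript length, and it was used only to derive relative transcript lengths. The further deposited count was read as reads near the 3′ end: of 4904 isoform pairs that share only their 3′ end 4560 had the same value, against 26 of 1274 pairs that share only their 5′ end. A read shared by isoforms is counted in each of them, and genes with near-identical copies may share reads. None of the 1559 transcripts on alternative haplotypes or unplaced contigs had reads in any library.

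For each gene symbol the transcript with the most reads over the 4 libraries was used, which gave 18895 symbols, 5875 of them with more than 1 transcript. Of these 10 had no usable symbol or position and were left out. Genes with at least 1 CPM in at least 1 library were kept, 13657 in all. Libraries were scaled by TMM in edgeR, with factors of 0.936 and 0.927 for MDA-MB-231 without and with serum and 1.08 and 1.07 for the libraries labelled MDA-MB-453. Coordinates are those of the deposited tables on hg19, counted from 1, from transcript start to end.

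For 1 library against 1 no test was made. The log2 ratio was taken with a prior of 0.5 reads per library, with an exact Clopper-Pearson 95% interval of the share of the pair's reads. A gene counted as higher or lower where the ratio was at least 2-fold and the interval excluded no difference. The difference of the 2 responses has a Wald 95% interval from the 4 counts. These intervals and the floor of 3 counts cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. A gene with 0 reads in both libraries of the MDA-MB-453 label gets a log2 ratio of 0.28, because the prior is the same for libraries of different depth.

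The serum effect common to both lines and the line effect were tested with edgeR's quasi-likelihood test on line plus serum, with Benjamini-Hochberg adjustment at 0.05 and 1 residual degree of freedom. The p-values measure only the spread between these 4 samples, which is confounded with any difference between the lines' responses. The design pairs the serum libraries by line, and this pairing comes from the labels. An interaction of line and serum leaves no residual degree of freedom and was not tested.

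In total 37 gene lists were fixed, of which 35 had at least 5 kept members and were tested. Each list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list stood apart where its median fell outside the central 95% of these. The percentile describes these libraries and is not a p-value. The 35 lists were read in 4 contrasts, 140 comparisons. Genes were named by rule: the 12 highest and 12 lowest genes of each line's response and the 10 each way of the contrast of responses by the interval bound nearest to no difference, the 10 largest each way past the edgeR threshold or all that passed, up to 4 members with at least 50 reads of each list described, and 26 genes by name for line identity and tube formation. Uncharacterised, antisense, pseudogene and Y-linked symbols were passed over. The groups, lists, tests, naming rule and most alternatives were fixed before the data were examined. The lineage lists of luminal, basal, melanocyte, neuronal, kidney, stem cell, muscle, hepatocyte, leukocyte and fibroblast genes, and KRT19 as a marker of identity, were chosen after NEFL and SALL1 had been seen. The lists of LXR and retinoic acid targets were written after ABCA1 and RARB had been seen and before their own values were.

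The procedure was tested on simulated data drawn from these libraries' means. Changed genes were drawn from those with at least 50 reads in each library, so recovery at lower counts was not tested. For the MDA-MB-231 response 97% to 100% of 200 genes changed by 1.5 or 2 on the log2 scale were recovered. For the contrast of responses 91% to 100% were recovered, and for the shared effect 100%. The line effect was recovered for 100% of 642 genes with as many reads whose line means differed by at least 2 on the log2 scale. Intervals covered the true value for 95.4% of genes with at least 10 reads over the pair, in counts simulated with counting error alone. Of 100 lists without an effect 6 stood apart. Unchanged libraries were simulated 20 times with counting error alone and with a dispersion of 0.00727. This dispersion, the same for all genes, was fitted on line plus serum without replicates, so it does not measure the spread between unchanged cultures.

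Alternatives were DESeq2 size factors, library totals, no filter, a filter of 5 CPM, a prior of 5 reads, thinning to the smallest library, the whole interval beyond 2-fold, DESeq2's Wald test, no pairing term and unmatched random lists. Those added after the data were seen were reads near the 3′ end, the transcript with the fewest reads, detected list members with at least 10 reads, genes with at least 10 reads in each line and genes with at least 100 reads in each line for the correlation. GC content came from the longest transcript of each symbol in the reference annotation, and 12330 of the 13657 genes had GC content and length. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.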

Results

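The study asked which transcripts differ between breast cancer cells that do and do not arrange themselves into vessel-like structures, a behaviour called vascular mimicry. Per the labels, MDA-MB-231, a basal-like breast cancer line of mesenchymal character, does this on matrigel, a basement membrane extract, once serum is withdrawn. MDA-MB-453, a luminal breast cancer line known for its high HER2, is labelled as the line that does not. Poly(A) RNA was sequenced from 4 libraries, 1 for each line with 0% and with 10% serum after 24 h on matrigel. The reads assigned to genes numbered 9724826 in MDA-MB-231 without serum and 9558565 with serum. In the libraries labelled MDA-MB-453 they numbered 8193905 without and 9970087 with serum. Reads were found for 14567, 14413, 14724 and 14876 genes in the same order, and 13657 genes were kept. No group had a replicate, so a difference between 2 libraries is given with an exact 95% counting interval, which covers counting error only and compares those libraries, not the conditions. Log2 ratios are without serum over with serum unless another contrast is named.

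Before the serum comparisons, the genes that identify the lines were read in every library. SPDEF, a transcription factor of luminal epithelium, had 4 and 2 reads without and with serum in the libraries labelled MDA-MB-453 and 667 and 429 in MDA-MB-231. The simple epithelial keratins KRT8 and KRT19 had 33 and 58 and 2 and 5 reads under the MDA-MB-453 label, against 3546 and 3519 and 3151 and 2060 in MDA-MB-231. ERBB2, which encodes HER2, was at a like level in both lines, with 518 and 601 reads under the MDA-MB-453 label and 628 and 576 in MDA-MB-231 (line log2 difference 0.22, SE 0.11, edgeR adjusted p = 0.0823). GATA3 and FOXA1, transcription factors of luminal cells, were higher under the MDA-MB-453 label (log2 of MDA-MB-231 over that label −1.29 and −1.73, edgeR adjusted p = 5.24e-05 and 0.00016).

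The MDA-MB-231 libraries carried the genes that this line is known for. VIM, the intermediate filament of mesenchymal cells, was their most abundant gene, with 45371 and 43354 reads. CD44 and AXL, an adhesion receptor and a receptor kinase of mesenchymal cells, had 8687 and 10914 and 9582 and 11214 reads, against 5 and 8 and 10 and 8 under the MDA-MB-453 label. CAV1, the coat protein of caveolae, and EGFR were also higher in MDA-MB-231 than under the MDA-MB-453 label, by 5.44 (SE 0.12) and 4.81 (SE 0.12) on the log2 scale. SPDEF, KRT8 and KRT19 go against the MDA-MB-453 label, and ERBB2 was not higher under it than in MDA-MB-231. The libraries under it are therefore called labelled MDA-MB-453 throughout. Each direction drawn from them holds for the cells under that label, whatever their line.

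**Figure D1:**
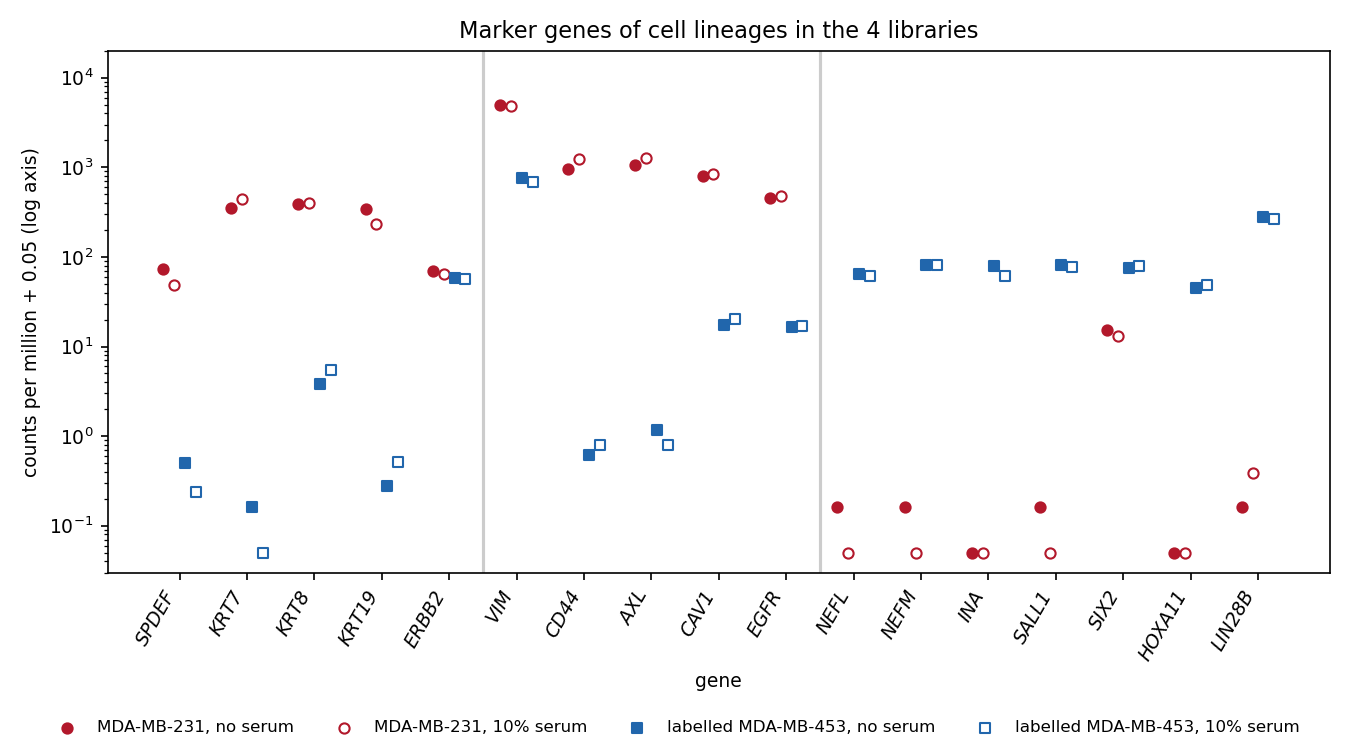
CPM plus 0.05, on a log axis, of marker genes in the 4 libraries, with circles for MDA-MB-231, squares for libraries labelled MDA-MB-453, filled without serum and open with 10% serum; the right-hand genes, from NEFL on, were chosen after their values were seen. SPDEF and KRT19 lie far below their MDA-MB-231 level in both libraries labelled MDA-MB-453, while NEFL, NEFM, INA, SALL1, HOXA11 and LIN28B lie far above their MDA-MB-231 level there.

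The 2 sets of libraries differed in most of the transcriptome. In the edgeR fit with serum as the paired term, 5067 genes were higher in MDA-MB-231 and 5198 were higher in the libraries labelled MDA-MB-453 at an adjusted p under 0.05, and 3186 of them differed by at least 4-fold. FAM111B was at least 958-fold higher in MDA-MB-231, with 1239 and 1409 reads against 0 and 0 and a floor of 3 counts over both libraries of a line, followed by FAM111A at least 810-fold, LTBR, the lymphotoxin beta receptor, at least 801-fold, and OCIAD2 at least 482-fold. The protease ADAMTS12, the transporter ABCC3, the epithelial transcription factor EHF and SAMD9L were at least 459-fold, 427-fold, 383-fold and 338-fold higher there. KRT7, a keratin of simple epithelia, had 3208 and 3928 reads against 1 and 0, a ratio of 7744 with a counting interval of 1390 to 305932. Values given as at least, here and below, rest on the floor of 3 counts and are not bounds of that kind of interval. The lower interval bounds were 778-fold for FAM111B, 658-fold for FAM111A and 651-fold for LTBR. In the other direction, BARX1 was at least 689-fold, BMP7 at least 582-fold, ZIC5 at least 548-fold, TBX3 at least 522-fold and CDX2 at least 485-fold higher under the MDA-MB-453 label, each with 0 reads in MDA-MB-231. BARX1, ZIC5, TBX3 and CDX2 are transcription factors of development, and BMP7 is a secreted growth factor. SLC19A1, a folate carrier, INA, a neuronal intermediate filament, PRAME, a tumour antigen, VANGL2, a planar polarity protein, and MYH14, a myosin, were at least 480-fold, 416-fold, 372-fold, 368-fold and 356-fold higher under that label.

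By fixed list, most genes of the interferon response, of inflammatory cytokines and NF-kB and of the extracellular matrix were higher in MDA-MB-231, with no test between lists. Of 25 interferon response genes 24 were higher in MDA-MB-231 and 1 was higher in the libraries labelled MDA-MB-453. OAS3, an antiviral enzyme, was at least 334-fold higher in MDA-MB-231. Of 19 NF-kB genes 18 were higher in MDA-MB-231 and 0 under the MDA-MB-453 label. Of 31 laminins, integrins and matrix genes 29 were higher in MDA-MB-231 and 1 under the MDA-MB-453 label. The ribosomal proteins went the other way, with 17 of 28 higher under that label and 3 higher in MDA-MB-231. The test had 1 residual degree of freedom, and its spread is the difference between the serum responses of the lines. With library totals in place of TMM factors every value moved by −0.20 towards the MDA-MB-453 label, and the counts became 4323 and 6164.

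In MDA-MB-231, genes of cholesterol synthesis and uptake stood out as higher without serum. HMGCS1, the enzyme that feeds acetyl-CoA into the mevalonate pathway, had 6763 reads without and 817 with serum, a log2 ratio of 3.01 (interval 2.91 to 3.12). It was followed by the sterol demethylation enzyme SC4MOL at 2.40 (2.28 to 2.51), the squalene epoxidase SQLE at 2.19 on 1248 and 265 reads and INSIG1, which retains the SREBP transcription factors in the endoplasmic reticulum, at 1.94 (1.86 to 2.02). Of the 25 list members 21 were at least 2-fold higher and 24 had an interval above 0. PMVK was the exception at −0.01 (−0.22 to 0.21). The list median was 1.74, at percentile 100 of 10000 random lists matched on expression. HMGCS1 (NM_001098272) lies on chromosome 5 at 43289494 to 43313595 of hg19, on the minus strand.

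Fatty acid synthesis was higher in MDA-MB-231 without serum as well. SCD, the desaturase that makes oleate, had the highest count of the list, 14675 reads without against 2563 with serum, a log2 ratio of 2.48 (2.42 to 2.54). ACSS2, which makes acetyl-CoA from acetate, had 1335 and 324 reads (interval of the log2 ratio 1.83 to 2.18), while ELOVL5 and GPAM were at 0.06 and −0.15 with intervals that included 0. The list median of 15 genes was 0.63, at percentile 100, with 11 intervals above 0 and 0 below. First of all genes by the interval bound nearest to no difference was SLCO4C1, an organic anion transporter (NM_180991, chromosome 5, 101569694 to 101632253), with 254 reads without and 12 with serum, 4.31 (3.54 to 5.34). LPIN1, a phosphatidate phosphatase, was at 2.08 (1.95 to 2.21), LIPG, the endothelial lipase, at 2.13 (1.82 to 2.46), and the sterol enzymes CYP51A1 and MVK at 1.84 and 1.93.

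Single genes of protease inhibitors, cytokines and a collagenase were among the lowest in MDA-MB-231 without serum, though the fixed list of matrix proteases and inhibitors as a whole was not lower, with a median of 0.08 and 9 intervals above 0 and 6 below. The protease inhibitor SERPINB2 was at −2.11 (−2.78 to −1.52), the cytokine IL24 at −2.69 (−4.05 to −1.68) on 8 and 53 reads, and INHBA, a subunit of activin, at −1.73 (−2.51 to −1.04). MMP1, an interstitial collagenase, was at −1.16, CYP1A1, an enzyme induced by the aryl hydrocarbon receptor, at −1.30, POLR3G, a subunit of RNA polymerase III, at −1.25 and the matrix protein THBS1 at −0.90 (−0.94 to −0.87) on 8554 and 15596 reads. MARCH4, KIAA1199 and RELN were at −1.26, −1.10 and −2.40, with MARCH4 at −0.57 when only reads near the 3′ end were counted, and ESM1 at −2.44 (−5.03 to −0.85) on 3 and 18 reads.

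Across all kept genes, 251 were at least 2-fold higher and 42 at least 2-fold lower in MDA-MB-231 without serum. Among genes with 100 or more reads these were 94 and 9. Libraries simulated with no difference gave 24.1 higher and 22.55 lower on average from counting alone. With a single dispersion for all genes, fitted on line plus serum, they gave 31.95 and 27.95. The 42 lower calls lie a little above these simulated counts. No replicate dish shows the spread between unchanged cultures, so how many calls such cultures would give is not known. With the whole interval required beyond 2-fold the counts were 58 and 6, and with a filter of 5 CPM they were 165 and 22.

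Gene groups of growth were lower in MDA-MB-231 without serum by small amounts that many members shared. All 21 genes of ribosome biogenesis had intervals below 0, with a list median of −0.50 at percentile 0, from POLR1A, the large subunit of RNA polymerase I, at −0.24 to the ribosomal RNA processing factor RRP12 at −0.70 (−0.85 to −0.54). All 28 ribosomal protein genes had intervals below 0, with a median of −0.32 at percentile 0, but after correction for GC content and transcript length that median was −0.17. Of 26 G2 and M phase genes 24 had intervals below 0, with a median of −0.25 at percentile 0.01 and CDC20, an activator of the anaphase-promoting complex, at −0.71 (−0.80 to −0.62). Genes of DNA replication had a median of −0.17 at percentile 1.03, with 18 of 29 intervals below 0. Inflammatory cytokines and NF-kB genes had a median of −0.32 at percentile 0.08, with IL8, a neutrophil chemokine, at −0.98 (−1.29 to −0.69). Metallothioneins, metal-binding proteins, had a median of −0.35 at percentile 0.6, with 3 of 7 intervals below 0.

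Other groups stood apart as higher in MDA-MB-231 without serum. NRF2 targets, genes of the oxidant response, had a median of 0.41 at percentile 100 with 13 of 18 intervals above 0, among them the ketosteroid reductase AKR1C3 at 0.87 (0.63 to 1.13). FOXO targets and quiescence genes had a median of 0.32 at percentile 100, with PIK3IP1, an inhibitor of PI3 kinase, at 2.24 (1.41 to 3.27) and KLF9 at −0.92 (−1.14 to −0.71). Laminins, integrins and matrix genes had a median of 0.32 at percentile 100, with the integrin subunits ITGB8 and ITGB3 at 1.57 and 1.13, 17 of 31 intervals above 0 and 8 below. Autophagy and lysosome genes had a median of 0.14 at percentile 100 and the protease CTSD at 0.63 (0.60 to 0.66). Immediate early genes had a median of 0.12 at percentile 98.5, with EGR1 at 0.94 (0.62 to 1.26) and FOS at 0.82. When only reads near the 3′ end were counted, the laminin and DNA replication lists no longer stood apart, at 0.16 and −0.14. Against random lists not matched on expression, the immediate early and autophagy lists did not stand apart either.

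Genes tied to vascular mimicry and endothelium went both ways in MDA-MB-231. Of 35 kept list members 7 had intervals above 0 and 8 below, 0 were at least 2-fold higher or lower, and the median of −0.01 lay at percentile 43.5. PECAM1, an endothelial adhesion molecule, was at 0.73 (0.15 to 1.35) on 67 and 39 reads, and EPHA2, an ephrin receptor, at 0.08 (0.03 to 0.13) on 7128 and 6564 reads. The endothelial receptor TIE1 was at 0.65 (−0.49 to 1.90) and KDR, a VEGF receptor, at −0.11 (−0.59 to 0.36), so neither difference was detectable at this depth. VEGFA was at −0.20 (−0.29 to −0.11) and the membrane protease MMP14 at −0.01 (−0.06 to 0.05). F3, tissue factor, and NRP2, a neuropilin, were lowest among list members with at least 50 reads, at −0.67 and −0.82. The protease MMP2 had 2 reads in each MDA-MB-231 library, and CDH5, the cadherin of endothelial junctions, had 0 reads there and was not kept. In the libraries labelled MDA-MB-453 the list median was 0.02 at percentile 53.3.

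In the libraries labelled MDA-MB-453, the sterol exporters ABCA1 and ABCG1 and the transferrin receptor were among the genes higher without serum. ABCA1, which exports cholesterol to apolipoproteins (NM_005502, chromosome 9, 107543285 to 107690436), had 140 reads without and 46 with serum, a log2 ratio of 1.87 (1.39 to 2.39). ABCG1, another sterol exporter, was at 2.04 (0.86 to 3.57) on 25 and 7 reads. TFRC, the transferrin receptor that takes up iron (NM_003234, chromosome 3, 195776156 to 195808961), had 6075 and 3805 reads, 0.95 (0.89 to 1.01). SREBF1, the lipid synthesis regulator, was at 1.08 (0.75 to 1.41) and INSIG1 at 0.83 (0.74 to 0.92). The nuclear receptors NR4A1 and NR4A2 were at 0.97 and 1.05, the early gene FOSB at 1.08 (0.74 to 1.43), the phosphatase DUSP8 (0.77 to 1.23) had 419 and 254 reads, and the neuronal pentraxin NPTX1 was at 1.05. ANKRD24 had 16 and 2 reads (1.19 to 6.44), and CDRT1 had 8 reads without and 0 with serum.

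Lower under the MDA-MB-453 label without serum were genes that respond to YAP and to TGF-beta. CTGF, a matricellular protein (NM_001901, chromosome 6, 132269319 to 132272518), had 100 reads without and 311 with serum, −1.36 (−1.70 to −1.03). The related CYR61 was at −0.66 (−0.86 to −0.47), the kinase NUAK2 at −1.38 (−2.18 to −0.67) and SKIL, a repressor of SMAD signalling, at −0.72 (−0.91 to −0.53). The chaperone CLU was at −0.74 and the mitochondrial carrier UCP2 at −0.66. ETV4 was at −2.13 (−4.72 to −0.53) on 3 and 18 reads, and SYT15, DUSP15, MMAA, ZNF426 and CCDC113 were between −2.05 and −0.90. In all, 77 genes were at least 2-fold higher and 38 at least 2-fold lower, and 8 and 2 with 100 or more reads. Simulated unchanged libraries gave 22.75 and 23.6 from counting alone and 33.1 and 34.1 with the fitted dispersion. The 38 lower calls are near these simulated counts, which hold no measured spread between replicate dishes. With the whole interval required beyond 2-fold the counts were 3 and 1.

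Several gene groups also stood apart under the MDA-MB-453 label. Cholesterol genes had a median of 0.20 at percentile 100, with 13 of 25 intervals above 0 and 0 at least 2-fold higher, led by INSIG1. Fatty acid synthesis had a median of 0.12 at percentile 99.8 and FOXO targets 0.15 at percentile 99.9, with the cell cycle inhibitor CDKN1A at 0.80 (0.54 to 1.06). Immediate early genes had a median of 0.28 at percentile 100, with EGR3 at 1.21 (0.55 to 1.92). DNA replication genes had a median of 0.10 at percentile 100, with 13 of 29 intervals above 0 and 1 below, and the licensing factor CDT1 at 0.38 (0.27 to 0.49). G2 and M phase genes had a median of −0.09 at percentile 0.37, laminins and integrins 0.09 at 99.5 and autophagy 0.07 at 98.1. With reads near the 3′ end the laminin median was −0.05, and the fatty acid and G2 and M lists no longer stood apart. The autophagy list no longer stood apart with a filter of 5 CPM, after thinning or against random lists not matched on expression, nor did the fatty acid, laminin and heat shock lists against unmatched lists.

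YAP and TEAD targets had a median of −0.21 at percentile 0 under the MDA-MB-453 label, with 8 of 22 intervals below 0 and 1 above, and of −0.13 at percentile 0.12 on the 21 members with at least 10 reads. In MDA-MB-231 the YAP list was at −0.13 and percentile 3.54, with 12 of 22 intervals below 0 and 4 above, and did not stand apart. It did so there against unmatched random lists, with reads near the 3′ end and with the transcript with the fewest reads. Under the MDA-MB-453 label TGF-beta targets had a median of −0.16 at percentile 0.12, with the latent TGF-beta binding protein LTBP2 higher at 0.75 (0.20 to 1.32). The unfolded protein response had a median of −0.13 at percentile 0.16, with SDF2L1, an endoplasmic reticulum protein, lowest at −0.45 and the transcription factor XBP1 highest at 0.27, and heat shock genes had −0.13 at percentile 0.91, with HSPA1B at −0.40. Neither of these 2 lists stood apart with reads near the 3′ end. Replication-dependent histones, whose poly(A) reads track RNA quality, had a median of 0.62 at percentile 100 on 8 genes, 3 of them with intervals above 0, and did not stand apart with no filter. Genes with 0 reads in both libraries get a log2 ratio of 0.28 from the prior alone, and this set the interferon median of 0.28 at percentile 99.6. Among the 12 interferon genes with at least 10 reads the median was −0.01 at percentile 38.6. The glucocorticoid receptor list went from 0.18 at percentile 99.8 to 0.09 at 94.3 in the same way, and NF-kB genes from 0.28 at percentile 96.0 to 0.40 at 100 on 7 genes.

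The contrast of the 2 responses, MDA-MB-231 minus the libraries labelled MDA-MB-453, was again led by sterol and fatty acid synthesis. SLCO4C1 differed by 4.32 (3.11 to 5.52), or by 2.57 with reads near the 3′ end, HMGCS1 by 2.85, SC4MOL by 2.34 (2.10 to 2.57), SCD by 2.29 (2.21 to 2.36), SQLE by 2.16 (1.95 to 2.37) and ACSS2 by 2.13. FDFT1, the squalene synthase, SC5DL, a sterol desaturase, LPIN1 and CYP51A1 differed by 1.77, 1.76, 1.78 and 1.65. Of the 25 cholesterol genes 24 had an interval of the difference above 0, with a median of 1.36 at percentile 100. The opposite sign belonged to ABCA1 at −2.58 (−3.15 to −2.02), HDAC9, a histone deacetylase, at −2.14 (−3.32 to −0.96), KHDC1 at −2.38, ASGR1 at −2.39, KIAA1199 at −2.03, DUSP8 with an interval of −3.15 to −0.85, the crosslinking enzyme TGM2 at −1.57, the chemokine receptor CXCR4 at −1.24 and TFRC at −1.01 (−1.09 to −0.94). THBS1 was at −1.88 (−2.82 to −0.93) on 23 and 14 reads under the MDA-MB-453 label, and at 0.92 when only reads near the 3′ end were counted.

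Between the responses, ribosome biogenesis differed by a median of −0.44 and ribosomal proteins by −0.31, both at percentile 0 with every member's interval below 0. DNA replication differed by −0.27 at percentile 0, G2 and M genes by −0.17 at 0.58, NF-kB genes by −0.78 at 0.01 and histones by −0.80 at 0.12. For the 7 NF-kB genes with at least 10 reads in each line the median was −0.40. Higher in the contrast were fatty acid synthesis at 0.58, NRF2 targets at 0.24, matrix proteases and inhibitors at 0.21, laminins and integrins at 0.13, autophagy at 0.10 and hypoxia and glycolysis at 0.09. Against random lists not matched on expression the laminin, autophagy and hypoxia lists did not stand apart in this contrast, and neither did the hypoxia list with reads near the 3′ end. The glycolytic enzymes ALDOC and PFKFB4 were highest of the hypoxia list among members with at least 50 reads, both at 1.43. Fibroblast markers had a median of 0.92 on 5 genes, which became −0.05 with a prior of 5 reads. In all 214 genes were higher and 88 lower by the 2-fold rule. Simulated unchanged libraries gave 38.4 and 42.2 from counting alone and 67.45 and 71.35 with the fitted dispersion, which holds no measured spread between replicate dishes. With a prior of 5 reads the counts were 114 and 46, and with the whole interval beyond 2-fold they were 24 and 2. No replicate exists to test these differences.

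**Figure D2:**
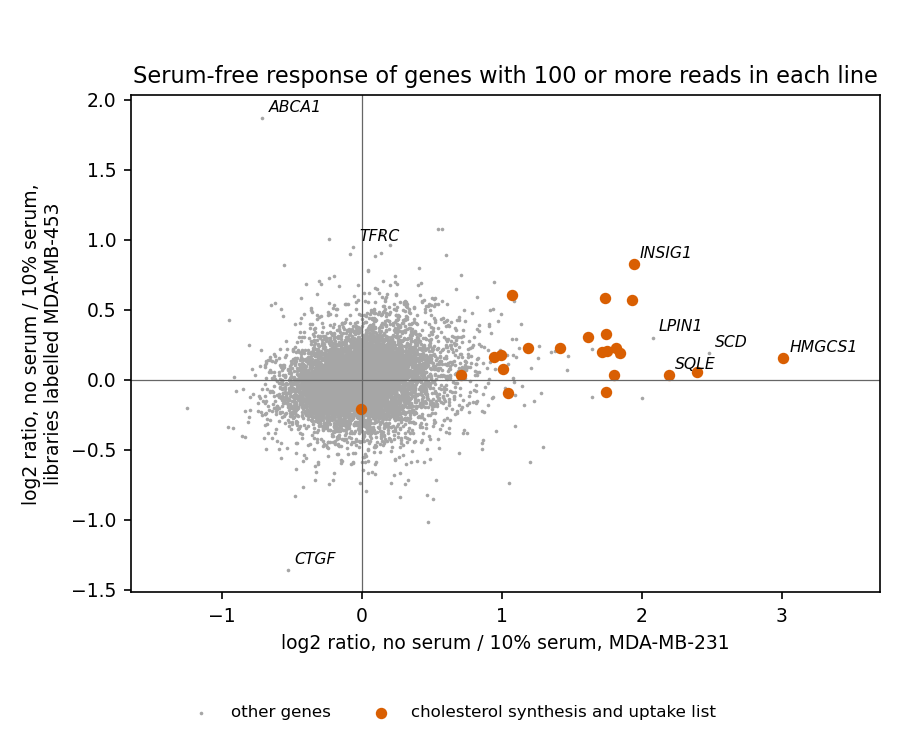
Log2 ratio without over with serum in MDA-MB-231 (x axis) against that in the libraries labelled MDA-MB-453 (y axis) for the 9612 genes with 100 or more reads in each line, 1 point per gene, with the cholesterol list in orange. HMGCS1 reaches 3.01 on the x axis and 0.16 on the y axis, and ABCA1 lies at −0.71 and 1.87.

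Serum withdrawal had an effect shared by both lines in few genes by the edgeR test, with 1 higher and 1 lower without serum at an adjusted p under 0.05 over 13657 genes. Among the 11895 genes with at least 10 reads in each line edgeR called 0 higher and 0 lower. Over all genes 1148 had an unadjusted p under 0.05, and DESeq2 called 14 higher and 5 lower. The lower call ended with library totals and with a filter of 5 CPM. Without the line as the paired term edgeR called 0 genes.

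In the fixed lists, many genes of lipid synthesis passed the shared test, largely through their response in MDA-MB-231. Under the MDA-MB-453 label SQLE, FDFT1, SC5DL and ACSS2, which passed, were at 0.03, 0.03, 0.05 and −0.13 with intervals that included 0. Adjusted over the list alone, 23 of 25 cholesterol genes passed in edgeR, against 1 over all genes tested, and 9 fatty acid genes against 0. So did 8 FOXO targets against 0 and 8 laminin and matrix genes against 0. Adjusted over the list alone, 8 TGF-beta targets passed against 1 over all genes, as did 5 matrix proteases and inhibitors against 1, and 4 each of YAP targets, NF-kB genes and epithelial genes against 0. For p53 and NRF2 targets 2 each passed, and 1 each for immediate early, hypoxia, glucocorticoid receptor and fibroblast genes, against 0 over all genes. Several of these passed on MDA-MB-231 alone, with fewer than 10 reads under the MDA-MB-453 label: the epithelial genes KRT19, SPDEF, TFF3 and AGR2, the NF-kB genes IL6, IL8 and IL24, the NRF2 targets AKR1B10 and AKR1C3, and MMP1, SERPINB2, INHBA and PDGFRB. Medians of the shared effect also stood apart for actin cytoskeleton genes at −0.11 and percentile 1.74, YAP targets at −0.15, metallothioneins at −0.32 and iron genes at 0.08. The actin list no longer stood apart with a filter of 5 CPM, with no filter, among detected members or with reads near the 3′ end. The iron list no longer stood apart with a filter of 5 CPM, with the transcript with the fewest reads or against random lists not matched on expression. The metallothionein median was 0.0044 on the 5 members with at least 10 reads in each line, and the iron median was −0.0095 with reads near the 3′ end.

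Few genes passed the 2-fold rule in both lines. C2, a complement protein, C4orf34 and GPR35 were at least 2-fold higher in both, against 1.42 expected of independent calls, and these 3 were chosen by their values. The other combinations of direction held 0 genes. Across genes, which are not independent replicates, the responses had a Pearson correlation of 0.0701 and a Spearman correlation of 0.147 over 13657 genes. Over the 9612 genes with 100 or more reads in each line these were 0.193 and 0.205, and without the cholesterol list 0.184 and 0.202. Of the 35 lists tested, 7 stood apart as higher and 6 as lower in MDA-MB-231, and 10 as higher and 5 as lower under the MDA-MB-453 label. Of those apart in both, 7 went the same way in both lines and 1, DNA replication, went opposite ways.

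**Figure D3:**
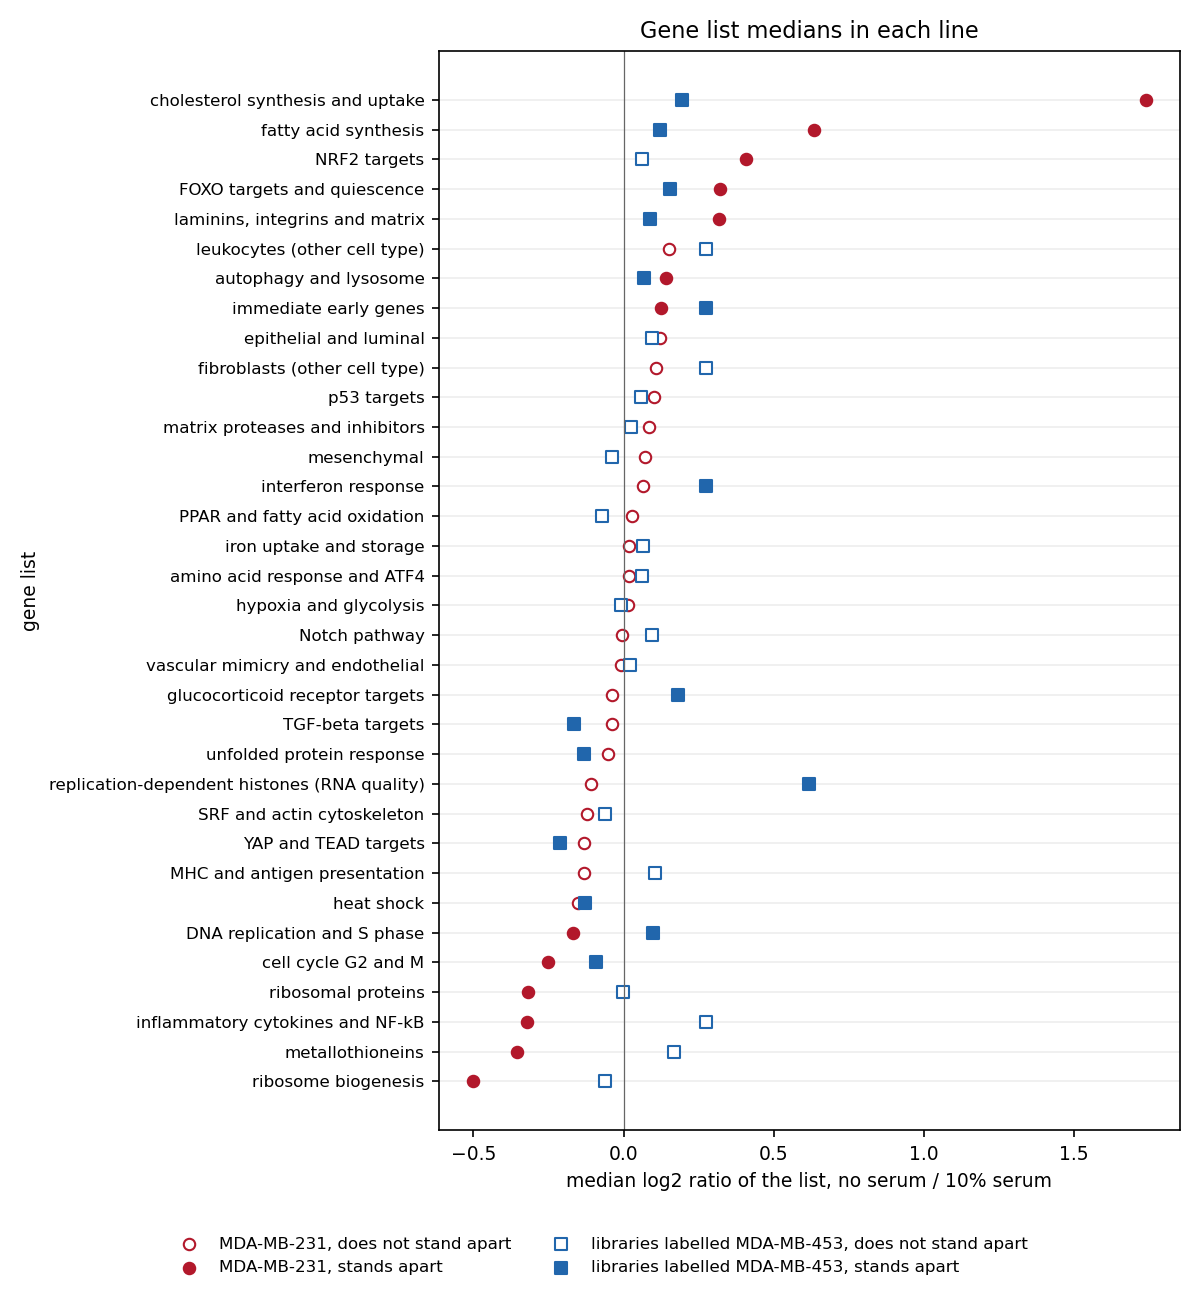
Median log2 ratio without over with serum (x axis) of gene lists (y axis), with circles for MDA-MB-231 and squares for libraries labelled MDA-MB-453, filled where the median lay outside the central 95% of 10000 random lists. Cholesterol genes lie at 1.74 and 0.20 and ribosome biogenesis at −0.50 and −0.06, while squares at 0.28 for interferon, NF-kB, leukocyte and fibroblast genes come from members with 0 reads.

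The remaining lists stood apart in neither line's response. In MDA-MB-231 and under the MDA-MB-453 label their medians were 0.08 and 0.02 for matrix proteases, 0.01 and −0.01 for hypoxia, 0.02 and 0.06 for amino acid response, 0.10 and 0.06 for p53 targets and 0.03 and −0.07 for fatty acid oxidation. They were 0.12 and 0.10 for epithelial, 0.07 and −0.04 for mesenchymal, −0.01 and 0.09 for Notch, −0.13 and 0.10 for antigen presentation and −0.12 and −0.06 for actin cytoskeleton genes. Iron genes were at 0.02 and 0.06. Markers of other cell types were scarce, and CD68, a lysosomal protein that tumour lines also express, made up 1245 and 1202 of the 1328 and 1263 leukocyte-list reads in MDA-MB-231. The 16 leukocyte markers summed to 157 and 147 reads under the MDA-MB-453 label. Fibroblast markers summed to 531 and 436 reads in MDA-MB-231, where PDGFRB was at 1.19 (0.74 to 1.68), and to 367 and 403 under the MDA-MB-453 label. Erythroid genes had 17 reads over the 4 libraries and were not kept, and 0 of the 13 mitochondrially encoded genes had a value here. The share of gene reads near the 3′ end was 33.7%, 34.7%, 34.7% and 34.8%, and the 10 most abundant genes took 3.53%, 3.28%, 2.66% and 2.69% of reads.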

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

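The tests of luminal genes, of GC content and length, of scaling as a cause and of reads near the 3′ end were chosen only after the result was seen.

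The libraries labelled MDA-MB-453 lack part of the transcripts of luminal breast cells, with 7 of 15 luminal genes under 1 CPM in both, as cells of another line under the label would give. Another 5 of the 15, ERBB2, GATA3, KRT18, TFAP2A and XBP1, were above 10 CPM in both libraries under the label. All of these were also above 10 CPM in both MDA-MB-231 libraries, where 10 of the 15 were, so they do not mark a luminal line here. ERBB2 was at 58.8 and 56.3 CPM under the label and 69.0 and 65.0 in MDA-MB-231, though MDA-MB-453 is known for high HER2. FOXA1, at 9.64 and 10.03 CPM under the label, just missed this bound, and was at 3.08 and 2.82 in MDA-MB-231. In MDA-MB-231 4 of the 15 were under 1 CPM as well, so a low count by itself does not name a line. A pipeline that does not count luminal transcripts is argued against by KRT7, KRT19 and SPDEF in MDA-MB-231, where none of them had fewer than 429 reads. Above 10 CPM in both libraries stood 5 of 12 neuronal genes, such as NEFL with 567 and 657 reads, 5 of 11 kidney and nephron progenitor genes, such as SALL1 with 716 and 816, and 2 of 8 stem cell genes, such as LIN28B with 2459 and 2847, against 6 of 14 basal and mesenchymal, 1 of 8 melanocyte and 0 skeletal muscle, hepatocyte, leukocyte or fibroblast genes. These data may therefore hold cells of another line, or a variant of MDA-MB-453 that lost part of its luminal programme, which were not told apart because no profile of either was compared.

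The cholesterol genes of MDA-MB-231 were higher without serum by a list median of 1.74. The choice of scaling is argued against, as the lowest median with DESeq2 size factors or library totals was also 1.74. Those scalings moved every MDA-MB-231 log2 ratio by only 0.0027 and 0.0136, so this test could not reach a factor common to all scalings. GC content and transcript length are argued against, with a median of 1.76 after correction in the 23 of 25 genes that have both values, and so is transcript coverage or RNA quality, with 1.68 from reads near the 3′ end. Withdrawal of serum, which the design names and which removes lipoprotein cholesterol from the medium, is a candidate explanation, as a hypothesis, and culture differences between 2 single dishes stay open. Whether the genes have to do with vessel-like structures was not tested.

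Ribosomal protein genes were lower without serum in MDA-MB-231 by a median of −0.32, and ribosome biogenesis genes by −0.50. The choice of scaling is argued against, with −0.30 as the highest ribosomal protein median under other scalings. A factor common to all scalings was again not reached by this test. For ribosomal proteins, GC content and transcript length cannot be told apart from an effect of serum: the median after correction was −0.17 with quartiles of −0.24 and −0.13, or −0.14 where the fit included the list, as it first did before the bound was tightened. For ribosome biogenesis the corrected median was −0.44 with an upper quartile of −0.35, which argues against these properties as the whole cause. Slower growth without serum could account for it, as a hypothesis.

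Some responses had intervals on opposite sides of 0 in the 2 lines, with the difference itself not tested and MDA-MB-453 meaning the libraries so labelled. ABCA1 was at −0.71 in MDA-MB-231 and 1.87 in MDA-MB-453, a difference of −2.58. For TFRC, at −0.06 and 0.95, the difference was −1.01. HDAC9 was at −0.67 and 1.47, a difference of −2.14, and KHDC1 at −0.97 and 1.41, a difference of −2.38. VEGFA was at −0.20 and 0.31, a difference of −0.50. The other way, ETV4 was at 0.33 and −2.13 on 3 and 18 reads in MDA-MB-453, a difference of 2.46, CLU at 1.05 and −0.74, a difference of 1.79, and CYR61 at 0.27 and −0.66, a difference of 0.93. The DNA replication and S phase list stood apart both ways, at −0.17 and 0.10, with a median difference of −0.27, but with reads near the 3′ end the MDA-MB-231 list, at −0.14, no longer stood apart.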

How the results depend on the processing

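Reads near the 3′ end, the transcript with the fewest reads, detected members, and genes with at least 10 or at least 100 reads in each line were tests chosen only after the results were seen. Of the values recomputed under the alternatives, 1979 were as before, 8 were reversed, 34 became weaker, 28 stronger and 36 moved otherwise. The cause was not tested except where fewer genes or a stricter rule shows it. The line counts held within 1.5 times under all alternatives run. The shared effect was the least stable: its count of higher genes was 7 with DESeq2 size factors, 8 with no filter, 109 with reads near the 3′ end, 2 with the transcript with the fewest reads, 14 with DESeq2's Wald test, and 0 with no replicate block or with genes of at least 10 reads in each line. Its count of lower genes was 0 with library totals, with 5 CPM, with no replicate block and with 10 reads in each line, 28 with reads near the 3′ end and 5 with the Wald test. Without the pairing by serum the line counts, the only others run without a block, stayed within 1.5 times. A filter of 5 CPM gave 165 higher and 22 lower genes in MDA-MB-231 and 48 and 16 under the MDA-MB-453 label, as fewer genes were tested. The whole interval beyond 2-fold gave 58 and 6, 3 and 1, and 24 and 2 for MDA-MB-231, the MDA-MB-453 label and the contrast of responses. A prior of 5 reads gave 14 lower genes under the MDA-MB-453 label and 114 higher and 46 lower in the contrast. The Pearson correlation was 0.193 for genes with 100 reads in each line. Reversed were fibroblasts in the contrast, −0.051 with a prior of 5 reads and −0.69 with 3′ reads, interferon genes under the MDA-MB-453 label, −0.0025 after thinning and −0.015 for detected members, THBS1 in the contrast, 0.92, laminins under the MDA-MB-453 label, −0.054, and iron genes in the shared effect, −0.0095, the last 3 with 3′ reads, and metallothioneins in the shared effect, 0.0044 for detected members. Leaving out 1 library in turn leaves no residual degree of freedom, so it was not run as a test. Depth limits genes under about 50 reads, where intervals span a 2-fold difference.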

Other observations

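Of the tests in this part, those of LXR and retinoid targets were set before their results were seen, and the genes named were chosen only after their values were seen. Some single genes were higher without serum in MDA-MB-231. The salivary cystatins CST1 and CST4 were at 1.94 (1.52 to 2.41) and 1.86 (1.22 to 2.60), the gel-forming mucin MUC5B with an interval of 1.41 to 2.22 on 237 and 66 reads, the trefoil peptide TFF3 with one of 0.99 to 2.77 on 55 and 15 reads and AGR2, a disulfide isomerase of mucus-making cells, at 1.57 (1.27 to 1.88). SPDEF, a transcription factor of luminal epithelium, was at 0.60 (0.42 to 0.78). The integrin subunit ITGA10 was at 1.78 (1.51 to 2.07), the polarity protein LLGL2 at 1.83 on 358 and 98 reads, the desmosome protein JUP at 1.13 (0.94 to 1.32) and the actin-severing protein GSN at 1.15 (1.01 to 1.28). Lower without serum were the peptide KISS1 at −1.02 (−1.39 to −0.66), the cytokine IL6 at −0.84 (−1.08 to −0.62) and the BMP-responsive factors ID1 at −0.83 (−1.04 to −0.64) and ID3 at −0.86 (−1.11 to −0.62). These genes were not tested as a group, and the fixed epithelial and luminal list, which holds TFF3, AGR2 and SPDEF, did not stand apart in MDA-MB-231, with a median of 0.12 at percentile 76.2 and 6 of 23 intervals above 0.

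Under the MDA-MB-453 label, the ligand WNT11 (0.39 to 1.65) had 60 reads without and 36 with serum. HMOX1, which degrades haem, was at −0.65 (−0.88 to −0.42) on 242 and 459 reads, NRP1, a VEGF co-receptor, at −0.60 (−0.87 to −0.35) and the cytokine receptor OSMR at −0.75 (−1.27 to −0.26). In MDA-MB-231 NRP1 was at 0.31 (0.26 to 0.37) and OSMR at 0.31 (0.20 to 0.41). The difference between the lines was not tested for any of them.

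ABCA1, ABCG1 and SREBF1, higher under the MDA-MB-453 label without serum, are targets of the sterol receptor LXR, so a move of sterol sensing through LXR may be a candidate explanation. The other 12 LXR targets had a median of 0.14 at percentile 93.5, between the bounds set beforehand for and against it, which leaves the hypothesis open. MYLIP, a ubiquitin ligase, was at 0.75 (0.48 to 1.01), and SMPDL3A at −0.44 (−0.91 to 0.01). In MDA-MB-231, where ABCA1 was at −0.71, the same targets had a median of 0.33 at percentile 98.4 over 11 genes.

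RARB and CYP26A1, both induced by retinoic acid, were lower without serum under the MDA-MB-453 label, at −1.58 (−3.25 to −0.33) and −1.43 (−2.96 to −0.24), so loss of serum retinoids may be an explanation. The 9 other retinoic acid targets with at least 10 reads had a median of −0.14 at percentile 11.4, short of the 2.5 set for the hypothesis and past the 10 set against it. Of these HOXB4 and NRIP1 had intervals below 0, at −0.66 and −0.37, while RET and CYP26B1 were at 0.61 and 0.26.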
